A study of Homo sapiens with 6 samples.

How the data were processed

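Total RNA was sequenced from Panc-1 cells, an established line from a human pancreatic ductal adenocarcinoma (PDAC). The cells carried either a scrambled control hairpin (shSCR, 3 libraries) or a short hairpin RNA directed at RBM42 (shRBM42-1, 3 libraries). Groups and replicate numbers were taken from the sample titles, which call the libraries biological replicates. Nothing in the labels says how the cultures were separated, so p-values measure the spread between these libraries. Per the labels' protocols, RNA was purified with an RNeasy Plus Mini kit and 10 ng of it was made into libraries with a stranded SMARTer kit for total RNA (v3, Pico). A kit of this kind keeps RNAs without a poly(A) tail, and it marks the strand of each read.

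The deposited table holds whole-number read counts per gene for 60662 genes in 6 libraries. Per the file header, the authors made the counts with featureCounts 2.0.6 on the GENCODE release 33 annotation of hg38, with paired-end mode and with reads that overlap several genes given to each of them. No strand option and no pair counting stand in that command, so both mates of a pair were counted and reads from antisense neighbours cannot be told apart. Among genes with 2 to 20 counts, the share of even counts lay between 79.4% and 81.9% in the 6 libraries. The submitters' processing notes also name Salmon and DESeq2, and the aligner is not given in the sources used here. Exons of 30.1% of the genes overlap another gene, and such overlaps of at least 10% of the exon length are given beside the genes named. All 37 mitochondrially encoded genes had 0 counts in all libraries, and each entry of the table names a gene. Symbols were found for 60402 of the gene identifiers. Gene types, GC content and transcript sequences came from GENCODE release 29, which covers 58489 of the identifiers.

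The total count per library was 43148158, 41516082 and 42350585 in shSCR replicates 1, 2 and 3, and 46870072, 36018999 and 40167819 in shRBM42-1 replicates 1, 2 and 3. A floor of 3 counts corresponded to between 0.064 and 0.0833 CPM (counts scaled to library size). Counting error alone is therefore small for genes far above this floor and large for genes near it, such as CD14 at 0.381 CPM in shSCR, and mates counted separately make it larger than the counts imply. Chi-square tests over genes found no pair of libraries that agreed within sampling noise, the lowest value being 28.3 per gene.

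Counts were tested with edgeR 4.0.16 in R 4.3.3, by its two-sided quasi-likelihood test on group alone. Genes were filtered with filterByExpr at default settings, which left 20601, and library sizes were scaled with TMM factors. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05 on the adjusted p. A minimum change of 2-fold, a log2 fold change of at least 1 in size, was applied after the test. CPM values are TMM-scaled, and standard errors (SE) of log2 fold changes were derived from the test's F statistic. Of 32 gene lists fixed before the data were examined, the 31 with at least 5 tested members were compared with all other genes by limma's camera (limma 3.58.1), on log2 CPM with a prior count of 2. The preset inter-gene correlation was 0.01, and camera with an estimated correlation was run beside it. Fry, also run, tests whether a list's genes move on balance one way and does not compare the list with other genes, so its p-values answer another question than camera's. The tests, the lists, the alternative settings not named as added later and the rule for naming genes were all fixed before the data were examined.

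That rule names RBM42 and MYC always. It adds the 8 highest, the 8 lowest and the 8 smallest-p genes among coding genes past the threshold, with an average log2 CPM of at least 2 and no overlap between the groups' libraries. Up to 4 members with the smallest p are named from each list described, and MYC, JUN and ATF4 are named whatever their p. Another gene that the rule names is not reported here.

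Replicate numbers come from the titles and are shared by the groups, so whether they pair the libraries was checked before the fits were compared. Deviations from the group means correlated over genes at 0.466, 0.59 and 0.426 for libraries numbered 1, 2 and 3, against at most 0.086 for libraries with different numbers. Every pair lay above 0.1, so the numbers were taken to pair the libraries. The fit with the replicate number as a block (the replicate block) was one of the alternative settings, and its values stand beside the results where they change a call or a count. Adding the block lowered the common coefficient of variation between libraries from 22.1% to 8.1%.

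Other alternatives were RLE and upper-quartile factors, library totals alone, no low-count filter, and a stricter filter of 1 CPM in 3 libraries with a mean count of 50. Structural RNA genes (rRNA, 7SL, 7SK, RMRP, RPPH1, small RNAs and genes counted over them) were removed in another. DESeq2 1.42.0 and limma-voom replaced the test. Each library was left out in turn, and smooth trends on GC content and exon length were removed with and without the block. Alternatives added after seeing the data are named in the closing section, among them a search of coding sequences and 3' untranslated regions (UTRs) for short base words. The search took the longest coding transcript of each gene from GENCODE release 29, and 171 coding genes without an annotated 3' UTR were not searched.

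The scripts were tested on simulated data. With a simulated replicate effect, the fit without the block called 0% of genes changed 1.5-fold, 47.8% of those changed 2-fold and 93.9% of those changed 4-fold, over 20260 genes. The fit with the block called 86.6%, 100% and 100% of them, and 9 of 20060 unchanged genes. The changed genes, 67, 67 and 66 at these folds, had an average log2 CPM of at least 2. The replicate effect and the dispersions were those of the blocked fit of these data, so the simulation could not test whether the libraries are paired. Without a simulated replicate effect both fits called 95.5%, 100% and 100%. In the word search, a word planted with a log2 shift of -0.3 came out at rank 1 over 9737 genes, and the highest absolute z over 20 permutations was 4.87. Figures were drawn with matplotlib 3.10.9.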

Results

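Read counts per gene were available for 6 libraries of total RNA from Panc-1 cells, 3 with a scrambled hairpin (shSCR) and 3 with a hairpin against RBM42 (shRBM42-1). RBM42 is an RNA-binding protein with an RNA recognition motif. The labels state that the knockdown was made to learn what RBM42 does in PDAC cells, in a series on factors that make the translation of oncogene mRNAs specific. Libraries held between 36018999 and 46870072 counts.

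RBM42 itself, the hairpin's target, was strongly lower in all 3 shRBM42-1 libraries. The gene (ENSG00000126254.12, hg38 chromosome 19, 35629030 to 35637686, plus strand) had 125, 130.5 and 132.5 CPM in shSCR replicates 1 to 3, and 17.8, 17.4 and 20.8 CPM in shRBM42-1 replicates 1 to 3. The mean fell from 129.4 ± 3.77 to 18.7 ± 1.81 CPM (SD, n = 3 each), a 6.92-fold decrease. The log2 fold change was -2.79 (SE 0.13), with an adjusted p of 0.000243 in edgeR's quasi-likelihood test. In fits without the replicate block, RBM42 was the gene that stayed past the threshold whichever library was left out.

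Beyond RBM42, the knockdown libraries had lower expression of the giant scaffold proteins AHNAK and AHNAK2, of the cytokine receptor kinase JAK1, of the growth factor MDK and of the basement membrane protein NID1. They had higher expression of the dynein light chain DYNLRB1, the mitochondrial dehydrogenase HSD17B10 and the activin receptor ACVR2B. In all, 116 genes were lower and 30 were higher among 20601 tested, and 91 of these changed at least 2-fold, 78 of them downwards. With the replicate block, 2783 genes were lower, 2162 were higher and 367 changed at least 2-fold, and these calls included all 146 genes called without it, in the same direction. The groups' libraries did not overlap for 4117 genes, which is 20% of those tested, where chance gives 10% if the libraries are not paired. Single libraries were left out in fits that did not use the block. Without shSCR replicate 1, shSCR replicate 3, shRBM42-1 replicate 1 or shRBM42-1 replicate 3, edgeR called 7, 6, 1 and 1 genes, all lower. In these fits 2239, 1926, 1807 and 2047 genes had an unadjusted p below 0.05. Without shSCR replicate 2 or shRBM42-1 replicate 2 it called 161 and 156 genes. With the block, all 146 genes passed in the same direction whichever replicate number was left out of both groups. Scaling by library totals alone gave 49 lower and 22 higher genes.

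AHNAK was the most abundant gene among those named. It fell from 4848 ± 724 to 629.9 ± 86.4 CPM (SD, n = 3 each), 7.70-fold, with a log2 fold change of -2.94 (SE 0.20) and an adjusted p of 0.00224 in edgeR's test. AHNAK2 fell from 413 ± 182 to 54.5 ± 15.7 CPM (SD, n = 3 each), with a log2 fold change of -2.92 (SE 0.38). The genes lie on chromosome 11 (62433542 to 62556235, minus strand) and chromosome 14 (104937244 to 104978374, minus strand). JAK1 fell 3.65-fold, from 215 ± 33.6 to 59.0 ± 5.43 CPM. MDK fell 3.14-fold, from 156.7 ± 15.8 to 49.9 ± 3.11 CPM, and NID1 fell 3.69-fold, from 180.3 ± 47.9 to 48.9 ± 2.32 CPM. NUTF2, which carries Ran into the nucleus, fell 3.99-fold, from a mean of 56.4 CPM to 14.2 CPM. The imprinted gene MEST had a log2 fold change of -1.99 (SE 0.27), with 12.6% of MEST's exon length under another gene. FBXL16, an F-box protein, had one of -1.97 (SE 0.18). SLC26A10P, a relative of anion exchangers, fell by 1.76 on the log2 scale, with 50% of its exon length under B4GALNT1 on the opposite strand. By smallest p, the lower genes also included AATF, a nucleolar regulator of transcription, at -1.50 (SE 0.12), and CBX6, a Polycomb protein, at -1.44 (SE 0.12). The unconventional myosin MYO1C stood at -1.70 (SE 0.17), and VPS4A, the ATPase of the ESCRT machinery, at -1.25 (SE 0.12), with 21.9% of its exon length under COG8.

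Several of these mRNAs held the bases GCCCAA, which were searched for only after the values were seen. These bases were common: 53.2% of the searched mRNAs of genes not called without the block held them, as did 87.9% of those of the lower genes and 53.3% of those of the higher genes. The coding sequence of AHNAK held 101 copies and that of AHNAK2 held 74. The coding sequence and 3' UTR together held 8 copies in CBX6, 7 in FBXL16, 5 in JAK1, 4 in NID1 and 3 each in MYO1C and VPS4A. AATF and SLC26A10P held 2 copies, MDK and MEST held 1 and NUTF2 held 0. RBM42 and MYC each held 1 copy, in the coding sequence, and JUN and ATF4 held 0. Among the 8 highest genes, HSD17B10 held 2, DYNLRB1 and SESN3 held 1, and the other 5 held 0.

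Among the higher genes, DYNLRB1 rose 2.91-fold, from 29.9 ± 10.0 to 87.0 ± 6.95 CPM (SD, n = 3 each), with a log2 fold change of 1.54 (SE 0.22), an adjusted p of 0.0298 in edgeR's test, and 16.7% of its exon length under ITCH. HSD17B10 rose 2.55-fold, from 31.0 ± 8.51 to 79.2 ± 2.86 CPM. ACVR2B rose from 5.91 ± 1.27 to 17.1 ± 4.97 CPM. KLHDC3, a substrate receptor of a ubiquitin ligase, had a log2 fold change of 1.29 (SE 0.16), and the synaptotagmin SYT11 one of 1.31 (SE 0.16). The stress-response sestrin SESN3 stood at 1.35 (SE 0.23), the membrane protein PCNX2 at 1.24 (SE 0.19), and the carnitine transporter SLC22A5 at 1.16 (SE 0.18).

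**Figure D1:**
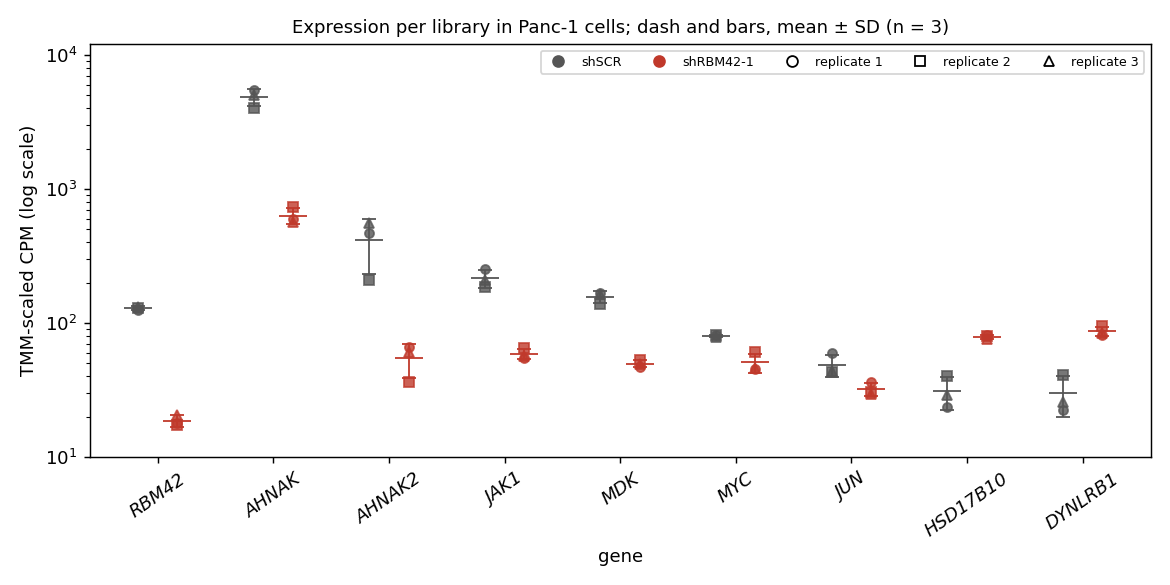
Expression of 9 genes in each library, as TMM-scaled CPM on a log axis; symbols mark the replicate numbers, colours the groups, and dashes with bars the mean ± SD (n = 3). RBM42 sat between 17.4 and 20.8 CPM in shRBM42-1 against 125 to 132.5 CPM in shSCR, and AHNAK at 564.6 to 727.9 CPM against 4041 to 5439 CPM.

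Of the oncogenic regulators named in advance, MYC and JUN had lower values in shRBM42-1. MYC had 80.1 ± 1.65 CPM in shSCR and 50.7 ± 8.36 CPM in shRBM42-1 (SD, n = 3 each), a log2 fold change of -0.66 (SE 0.14) with an adjusted p of 0.0894 in edgeR's test. JUN had 48.8 ± 9.32 and 32.0 ± 3.47 CPM, at -0.61 (SE 0.16) and an adjusted p of 0.153. With the replicate block both were past the threshold, MYC at -0.67 (SE 0.08, adjusted p = 2.23e-06) and JUN at -0.60 (SE 0.08, adjusted p = 6.69e-06). MYC was also past the threshold without shRBM42-1 replicate 2, at -0.80 (adjusted p = 0.0463). ATF4, a transcription factor of the amino acid response, stood at 0.25 (SE 0.30, adjusted p = 0.798), and at 0.23 (SE 0.07, adjusted p = 0.0213) with the block. ATF4 was not called with the block when replicate 1 or replicate 3 was left out of both groups (adjusted p = 0.107 and 0.114), and MYC and JUN were.

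Camera called 5 gene lists, all of them lower: histones, snoRNA host genes, ribosome biogenesis, G1/S and DNA replication, and MYC targets. Their estimated correlations were 0.908, 0.105, 0.21, 0.127 and 0.104 in that order, against the preset 0.01. Of the 10 ways to split the 6 libraries into groups of 3, 7 gave at least 5 lists, the real split among them. The replication-dependent histone genes had a median log2 fold change of -0.59, with 49 of 52 members below 0 (adjusted p = 7.36e-08, adjusted p = 0.961 with an estimated correlation). No single histone gene passed edgeR's threshold over all genes or adjusted over the list alone, while 12 had an unadjusted p below 0.05. DESeq2 called 4, with H4C9 higher and H1-4, H1-5 and H1-2 lower. With the replicate block, 46 were lower and 1 was higher. The linker histones H1-4 (-1.21, SE 0.08), H1-5 (-0.91, SE 0.08) and H1-2 (-0.87, SE 0.08) were lower in that fit, and H4C9 (0.63, SE 0.08) was the higher one. The histone median ranged from -0.89 without shRBM42-1 replicate 2 to -0.30 without shSCR replicate 2, and the list was called each time.

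The snoRNA host genes, whose introns carry the guide RNAs of ribosomal RNA modification, had a median of -0.43, with 24 of 25 members below 0 (adjusted p = 1.19e-05, adjusted p = 0.961 with an estimated correlation). None passed over all genes in edgeR's test, though 12 had an unadjusted p below 0.05 and DESeq2 called 1. Adjusted over the list alone 4 were lower, and 17 were lower and 1 higher with the block. GAS5 stood at -0.57 (SE 0.10) in the blocked fit, and SNHG32, with 23.2% of its exon length under another gene, at -0.40 (SE 0.08). SNHG7 stood at -0.66 and SNHG8 at -0.67 in it, with 30.3% and 37.6% of their exon length under DIPK1B and PRSS12. The ribosome biogenesis and nucleolus list had a median of -0.23, with 45 of 50 members below 0 (adjusted p = 1.57e-04, adjusted p = 0.961 with an estimated correlation). RRP1B fell by 0.99 on the log2 scale (SE 0.16, adjusted p = 0.0374) and was the 1 member lower over all genes, against 3 adjusted over the list alone and 25 with the block. BOP1 stood at -0.52 (SE 0.08), RRP9 at -0.34 (SE 0.08) and NOB1, with 20.4% of its exon length under NQO1-DT, at -0.51 (SE 0.07) in the blocked fit. There the 26 members with GCCCAA had a median of -0.30 and the 24 without -0.17. List medians split by GCCCAA, here and below, are of values without removal of GC content and length trends. They may also reflect those trends.

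The G1/S and DNA replication list had a median of -0.24, with 35 of 40 members below 0 (adjusted p = 0.00534, adjusted p = 0.961 with an estimated correlation). No member passed edgeR's test over all genes or adjusted over the list alone without the block, 7 had an unadjusted p below 0.05 and DESeq2 called 0. With the block 21 were lower, among them GINS2 (-0.63, SE 0.11), the helicase subunit MCM3 (-0.55, SE 0.07), RFC2 (-0.34, SE 0.07) and UNG (-0.29, SE 0.07). In the blocked fit the 15 members with GCCCAA had a median of -0.15 and the 25 without -0.27. Fry gave this list an adjusted p of 0.451 without the block and 0.00995 with it. Without shRBM42-1 replicate 2 the median was -0.15 and the camera adjusted p 0.0924, and without shSCR replicate 1 they were -0.13 and 0.039. With GC content and length trends removed in the blocked fit the median was -0.15 (adjusted p = 0.000345). Across the 9737 genes compared for base words, which are not independent replicates, the blocked log2 fold change and GC content had a Spearman rho of -0.361. Among the 4503 of these genes without GCCCAA, rho was -0.385. MYC targets outside the ribosome had a median of -0.13, with 30 of 40 members below 0 (adjusted p = 0.0351, adjusted p = 0.961 with an estimated correlation). The DNA repair enzyme APEX1 fell by 1.01 on the log2 scale (SE 0.13, adjusted p = 0.0257) and was the 1 member called over all genes, against 4 adjusted over the list alone. With the block 14 were lower and 3 higher, and HSPD1 (-1.05, SE 0.08), AHCY (-0.64, SE 0.07) and GART (-0.61, SE 0.08) were among the lower ones. In the same fit the median was -0.30 in the 14 members with GCCCAA and -0.034 in the 26 without. With genes holding these bases left out, the list was not called (-0.062, adjusted p = 0.35), and with GC content and length trends removed it was called at -0.075 (0.0162). It also missed the threshold without shSCR replicate 1 (adjusted p = 0.105), shSCR replicate 2 (0.0796), shRBM42-1 replicate 1 (0.0553) or shRBM42-1 replicate 3 (0.196), and with library totals alone (0.0822) or upper-quartile factors (0.058).

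The heat shock response list had a camera adjusted p of 0.0548 without the block and 0.027 with it, and with the block it was not called when replicate 1 was left out of both groups (-0.15, adjusted p = 0.254). Without shSCR replicate 3 it was 0.0219, and after correction for GC content and length 0.0327. The list's median was -0.26 over 19 members, 1 of which was lower over all genes, 2 adjusted over the list alone and 10 with the block. The 16 members whose mRNA held GCCCAA had a median of -0.275 in the blocked fit and included all 10 of the lower ones, and the other 3 had a median of 0.01. With genes holding these bases left out, too few members remained for a list test. HSF1, the transcription factor of this response, fell from 115.2 to 65.2 CPM, at -0.82 (SE 0.13, adjusted p = 0.0403), and HSPA1A stood at -0.40 (SE 0.07) and FKBP4 at -0.29 (SE 0.07) in the blocked fit. None of the 31 lists was called with an estimated correlation, where the adjusted p of each of these 6 lists was 0.961 without the block and 0.811 with it. Replicate 2 of both groups stood apart from the other libraries on the first principal component (41.2% of the variance), at 55.0 and 48.7 against -33.1 to -22.7. Structural RNAs took 19.9% and 18.2% of the counts in those libraries, against 7.35% to 14.1% in the others.

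**Figure D2:**
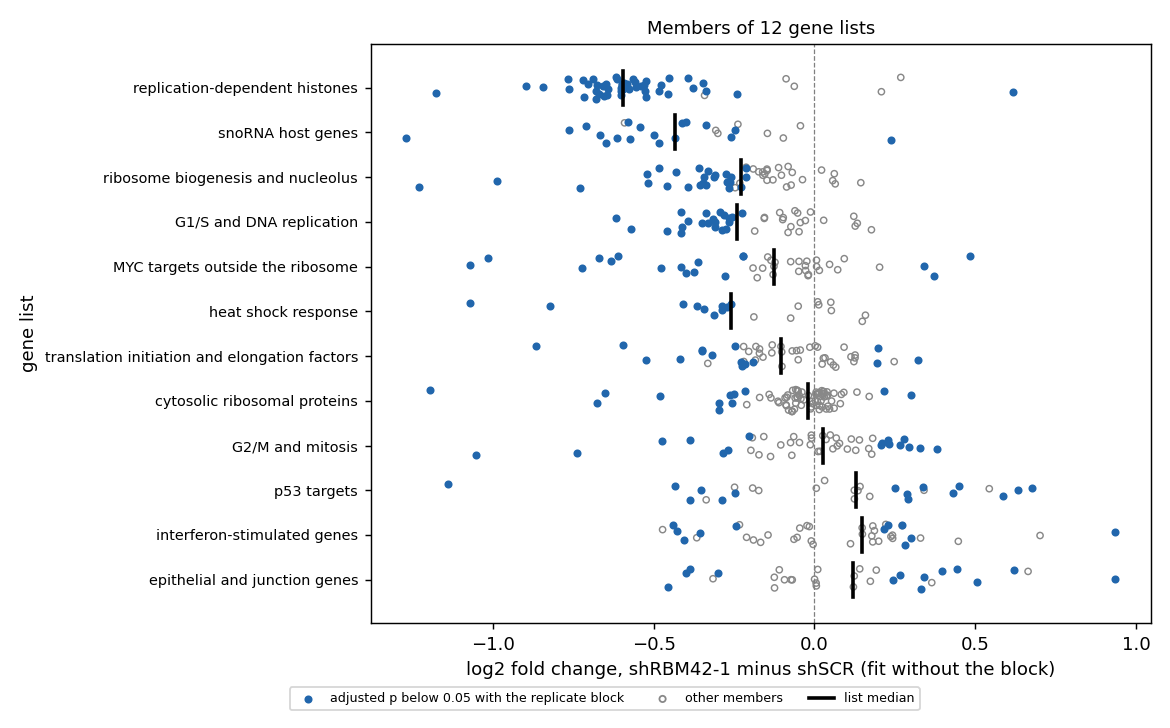
Log2 fold changes (shRBM42-1 minus shSCR, fit without the replicate block) of the members of 12 gene lists; filled points passed the threshold with the block, open points did not, and black bars mark list medians. The histone median lies at -0.59 and the snoRNA host gene median at -0.43, while the cytosolic ribosomal proteins centre on -0.02.

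Genes of the translation and splicing machinery were not called as lists with or without the block. Of 79 cytosolic ribosomal protein genes, RPL7A alone was lower over all genes, falling from 431 to 188.1 CPM (-1.20, SE 0.19, adjusted p = 0.0368), and the list's median was -0.02 (adjusted p = 0.59). That median was 0.05 with library totals alone and 0.01 with upper-quartile factors. The list was called lower without shSCR replicate 3 (-0.10, adjusted p = 0.0186) or shRBM42-1 replicate 2 (-0.16, 0.00343) and higher without shSCR replicate 2 (0.16, 0.0232). With the block 10 were lower and 2 higher, RPL32 (-0.70, SE 0.08), RPL29 (-0.66, SE 0.07) and RPL5 (-0.49, SE 0.08) among the lower ones. Translation initiation and elongation factors had a median of -0.10 (adjusted p = 0.301), which was -0.051 without shRBM42-1 replicate 1 and -0.057 without shSCR replicate 1, with 12 of 48 lower and 3 higher in the blocked fit, where EIF6, with 17.4% of its exon length under another gene, stood at -0.88 (SE 0.07) and EIF5 at -0.36 (SE 0.07). In that fit the median was -0.175, with 9 lower, in the 26 members with GCCCAA and -0.02, with 3 lower and 3 higher, in the 22 without, and with genes holding these bases left out the list's median was -0.045 (adjusted p = 0.79). In the list of tri-snRNP and core spliceosome proteins, median -0.02 (adjusted p = 0.951) and 0.04 with library totals alone, SF3A1 fell by 1.11 on the log2 scale (SE 0.15) and SNRNP27 rose by 0.83 (SE 0.11), with 12.5% of SNRNP27's exon length under MXD1. The other members of that list were not called, and with the block 8 of 43 were lower and 3 higher. The hnRNP and SR proteins (median -0.06, adjusted p = 0.581) had 6 of 40 members lower and 5 higher with the block. The RBM family list leaves out RBM42 itself. It (median 0.04, adjusted p = 0.751) had 7 of 38 lower and 6 higher with the block, RBMX2 at -0.47 (SE 0.08) and RBMS2 at 0.53 (SE 0.08). No member of these last lists was called by edgeR or by DESeq2 without the block, and 2 and 7 had an unadjusted p below 0.05. With GC content and length trends removed, the hnRNP and SR proteins were called lower at -0.135 (adjusted p = 0.0327), and at -0.137 (0.0117) with the block, where translation factors were called too, at -0.104 (0.0221). Both lists had an adjusted p of 0.962 with an estimated correlation, without that removal.

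Growth and stress pathways held single genes past the threshold in lists that were not called. FOSL1, an AP-1 subunit, fell from 305.2 to 122.1 CPM (-1.32, SE 0.16, adjusted p = 0.0199) in the immediate early list, whose median was 0.04 and adjusted p 0.846. In that list JUNB, with 14.2% of its exon length under HOOK2, stood at 0.60 (SE 0.10) and CCN2 at 0.61 (SE 0.10) with the block, where 5 of 32 were lower and 5 higher. GDF15, a stress-induced cytokine, fell from 44.2 to 20.04 CPM (-1.14, SE 0.13, adjusted p = 0.0195) in the p53 target list, whose median was 0.13 and adjusted p 0.32. With the block CDKN1A (0.63, SE 0.09), TP53INP1 (0.67, SE 0.11) and SESN1 (0.58, SE 0.10) were higher there, among 9 higher and 6 lower of 28. TOP2A fell by 1.05 on the log2 scale (SE 0.16, adjusted p = 0.0368) in the G2/M and mitosis list, median 0.03 (adjusted p = 0.942), with 7 of 45 lower and 9 higher with the block. FOXM1, with 15.9% of its exon length under ITFG2, stood at -0.73 (SE 0.08) in that fit. TGFBR2 rose by 0.78 (SE 0.12, adjusted p = 0.0368) in the list of PDAC oncogenes and tumour suppressors, median 0.09 (adjusted p = 0.669), where 6 of 33 were lower and 9 higher with the block. In that fit RNF43 stood at 0.99 (SE 0.16), with 57.6% of its exon length under another gene, and AKT2 at -0.62 (SE 0.07). The inflammatory and NF-kB list had a median of -0.20 (adjusted p = 0.136), and in the blocked fit, with 6 of 19 lower and 2 higher, ICAM1 stood at -0.81 (SE 0.08) and TNFAIP2 at -0.98 (SE 0.07). ICAM1 shares 23.6% of its exon length with ICAM4-AS1. This list was called lower without shSCR replicate 1 (adjusted p = 0.0226) or shRBM42-1 replicate 2 (0.0478), and fry gave it 0.451 without the block and 0.033 with it. With an estimated correlation and all 6 libraries its camera adjusted p was 0.961, and 0.811 with the block. Adjusted over the list alone, 1 immediate early gene, 2 G2/M genes and 2 inflammatory genes were lower, 3 p53 targets were higher and 1 lower, and 4 PDAC genes were higher and 5 lower.

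The remaining metabolic and cell-state lists were not called either. With the block, 9 of 24 genes of cholesterol synthesis and uptake were higher and 3 lower (median 0.06, adjusted p = 0.318), INSIG1 at -0.59 (SE 0.07) and STARD4 at 0.71 (SE 0.10). Of 31 epithelial and junction genes 9 were higher and 4 lower (median 0.12, adjusted p = 0.165), and of 41 mesenchymal and extracellular matrix genes 8 were higher and 4 lower (median 0.06, adjusted p = 0.365). Glycolysis and hypoxia genes (median 0.04, adjusted p = 0.374) included the lactate transporter SLC16A3 at 0.92 (SE 0.09), with 5 of 33 higher and 2 lower. Nuclear-encoded oxidative phosphorylation genes (median 0.08, adjusted p = 0.301) had 7 of 46 higher and 4 lower, with CYC1 at -0.79 (SE 0.07). The lists for interferon-stimulated genes (median 0.15, adjusted p = 0.332), lysosome and autophagy (0.04, adjusted p = 0.621), the unfolded protein response (0.03, adjusted p = 0.621), ATF4 targets (-0.05, adjusted p = 0.738) and NRF2 targets (-0.08, adjusted p = 0.59) were not called. The classical and basal-like PDAC signatures had 9 tested members each, with medians of 0.50 (adjusted p = 0.301) and 0.21 (adjusted p = 0.332). The classical median was 0.07 without shRBM42-1 replicate 1, 0.18 without shSCR replicate 3 and 0.64 without shSCR replicate 1, and the basal-like median was -0.10 without shRBM42-1 replicate 2. Median and mean differed in sign in the immediate early list and in the G2/M list (mean -0.015 and -0.018). Without shSCR replicate 3 or shRBM42-1 replicate 2 the epithelial list (adjusted p = 0.0219 and 0.0253) and the mesenchymal list (0.0186 and 0.0478) were called higher. The same held for oxidative phosphorylation without shSCR replicate 2 (0.00178) and for interferon-stimulated genes without shSCR replicate 1 (0.0226). Adjusted over the list alone, INSIG1 was the 1 gene of these lists that passed. The epithelial list was also called higher after correction for GC content and length (0.15, adjusted p = 0.0492), but not with that correction and the block (0.17, adjusted p = 0.0871). Its adjusted p with an estimated correlation was 0.961, and 0.811 with the block, and fry gave it 0.716 without the block and 0.0157 with it.

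Markers of other cell types gave no list past the threshold. Of 28 pancreatic acinar and endocrine markers 23 lay below the expression filter, and CHGB, the most abundant, reached 5.33 CPM in any library (list median 0.23, adjusted p = 0.951). Of 24 blood and endothelial markers 19 lay below it, with a list median of -0.42 (adjusted p = 0.951), and CD14, near the floor of counting, had 0.381 CPM in shSCR and 1.38 CPM in shRBM42-1. CD14 was not called over all genes (adjusted p = 0.0502), and was higher adjusted over the list alone (0.00193), by DESeq2 (0.00241) and with the block (0.000718). The means of these lists had the opposite sign, -0.032 and 0.091. The embryonic kidney and neural list kept 11 of 18 markers, with a median of -0.26 (adjusted p = 0.397) that was -0.043 without shRBM42-1 replicate 2, and LIN28B stood at 0.97 (SE 0.09, adjusted p = 1.28e-07) with the block. LIN28B was not called over all genes (0.101), and was higher adjusted over the list alone (0.0222) and by DESeq2 (0.00308). With the block 1 acinar and endocrine marker was higher, 1 blood and endothelial marker was higher and 1 lower, and 1 embryonic kidney and neural marker was higher and 2 lower.

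Past the threshold were 22 genes named for their size, for their p or in advance. Of these, 20 passed without shSCR replicate 2, 19 without shRBM42-1 replicate 2, 7 without shSCR replicate 1 and 6 without shSCR replicate 3. RBM42 alone passed without shRBM42-1 replicate 1 or shRBM42-1 replicate 3. No gene named from the lists was called without shSCR replicate 1 or 3, or without shRBM42-1 replicate 1 or 3. With the block all 146 genes passed in the same direction whichever replicate number was left out of both groups. AHNAK2, SLC26A10P, ACVR2B, SESN3 and PCNX2 missed the threshold with library totals alone, SESN3 and SLC22A5 after correction for GC content and length, SESN3 and SLC26A10P with limma-voom, SESN3 without both libraries of replicate 2, and ACVR2B and PCNX2 with genes holding GCCCAA left out.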

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

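The fits that left out both libraries of 1 replicate number, those that removed structural RNA genes together with the replicate block, and those that left out genes with GCCCAA, with either correlation in camera, were chosen after the data had been seen. RBM42 was lower and past the threshold in every setting that kept the gene; the fits without GCCCAA genes left it out, and no gene called without the block changed sign in the settings listed here. JUN passed with no low-count filter (adjusted p = 0.0386) and in all the blocked fits. ATF4 passed in the blocked fits other than those without replicate number 1 (0.107) or 3 (0.114). MYC passed with DESeq2, with no low-count filter, without shRBM42-1 replicate 2, without both libraries of replicate 2 and in the blocked fits that kept the gene.

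With the replicate block 2162 genes were higher, 2783 lower and 367 changed at least 2-fold, and the heat shock list was called at -0.265. Of the genes named for their size, for their p or in advance, MYC, JUN and ATF4 were called by edgeR with the block and not without it; it changed no other call among these, and no other among camera's list calls. It changed calls of many members named from lists, whose blocked values stand in the report. The block with GC content and length trends removed gave 2133 higher, 2467 lower, 320 at least 2-fold and 8 lists, with translation factors at -0.104, heat shock at -0.217 and hnRNP and SR proteins at -0.137 called. G2/M (0.0108), tri-snRNP proteins (-0.0237) and the RBM family (0.0113) took the other direction there. Removing those trends without the block gave 8 lists, with heat shock (-0.233), epithelial genes (0.147) and hnRNP and SR proteins (-0.135) added, and reversed G2/M (0.0185) and the RBM family (0.00927).

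Directions of lists refer to the test statistic, which can differ in sign from the median printed. Library totals alone gave 49 lower genes and 56 changed at least 2-fold, lost the MYC target list (-0.0735), and reversed tri-snRNP proteins (0.0393) and acinar and endocrine markers (0.269). Upper-quartile factors did the same for these lists, at -0.0961, 0.0132 and 0.261. With no low-count filter 145 genes were higher, 437 lower and 198 changed at least 2-fold, and G2/M (0.021), immediate early genes (0.0396), acinar and endocrine markers (-0.155) and blood and endothelial markers (0.251) were reversed. The stricter filter reversed tri-snRNP proteins (-0.0146). DESeq2 called 197 higher and 444 lower genes, 187 of them at least 2-fold, and limma-voom called the heat shock list (-0.264) and lost SESN3 and SLC26A10P. The cause of these differences was not tested.

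Camera with an estimated correlation called 0 lists and fry's test of 1 direction called 0, where the lists kept their medians of -0.594 for histones, -0.432 for snoRNA hosts, -0.229 for ribosome biogenesis, -0.24 for G1/S and -0.127 for MYC targets. Their adjusted p was 0.961 with the estimated correlation and between 0.242 and 0.703 with fry. With the block the estimated correlation again called 0 lists, and fry called 3: G1/S (adjusted p = 0.00995), epithelial (0.0157) and inflammatory genes (0.033). Fry gave the other direction for G2/M (0.0261), immediate early genes (0.0442) and blood and endothelial markers (-0.416).

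Without both libraries of replicate 2, 101 genes were higher, 410 lower and 177 changed at least 2-fold, with tri-snRNP proteins (-0.0103) and blood and endothelial markers (-0.268) reversed. With the block and without replicate number 1, 2 or 3 in both groups, 1515, 1911 and 1393 genes were higher, 1942, 2499 and 1796 lower, and 294, 423 and 296 changed at least 2-fold. Leaving out number 1 lost MYC targets (-0.0875), did not call heat shock (-0.151, adjusted p = 0.254) and reversed the unfolded protein response (0.00147), tri-snRNP proteins (0.015) and lysosome genes (0.0204). Leaving out number 2 called heat shock (-0.291) and reversed tri-snRNP proteins (-0.0108) and blood and endothelial markers (-0.231), and leaving out number 3 called heat shock (-0.246). Structural RNA genes removed with the block gave 2469 higher, 2631 lower, 360 at least 2-fold and heat shock at -0.249.

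Leaving out genes with GCCCAA left 10 higher and 23 lower genes, 22 of them at least 2-fold, and with the block 1100, 1268 and 190. Fewer genes were tested in these fits, 13266, among them genes that were not searched. GC content and length trends were not removed in them. Of the 25 snoRNA host genes 1 was searched, and it lacked the bases, so these fits could not test that list against them. Of the 52 histone genes 25 were searched, and 7 of these held the bases. MYC targets were lost (-0.0624, and -0.06 with the block), p53 targets (0.242 and 0.243) and interferon-stimulated genes (0.189 and 0.208) were called higher, and tri-snRNP proteins were reversed (0.0532 and 0.0606). Medians also moved to -0.0454 for translation factors, -0.0177 for epithelial genes, 0.0146 for mesenchymal genes and 0.152 for the unfolded protein response without the block. With an estimated correlation 0 lists were called in either fit, with medians of -0.605 and -0.611 for histones, -0.454 and -0.424 for snoRNA hosts, -0.22 and -0.2 for ribosome biogenesis and -0.299 and -0.298 for G1/S.

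Leaving out 1 library at a time, the higher genes ranged from 0 without shSCR replicate 1, shSCR replicate 3, shRBM42-1 replicate 1 or shRBM42-1 replicate 3 to 28 without shSCR replicate 2. The lower genes ranged from 1 without shRBM42-1 replicate 1 or 3 to 133 without shSCR replicate 2, and those changed at least 2-fold from 1 to 120. The lists called ranged from 4 to 9, the latter without shSCR replicate 3. Medians ranged from -0.163 to 0.16 for cytosolic ribosomal proteins, -0.164 to -0.0799 for MYC targets, -0.275 to -0.129 for G1/S, -0.0829 to 0.153 for G2/M and -0.0721 to 0.132 for the unfolded protein response. They ranged from -0.276 to -0.124 for heat shock, -0.185 to -0.0218 for NRF2 targets, 0.0241 to 0.197 for oxidative phosphorylation, -0.012 to 0.199 for interferon-stimulated genes and -0.339 to -0.117 for inflammatory genes. For immediate early genes the range was 0.00446 to 0.0981, for epithelial genes -0.0285 to 0.22, for mesenchymal genes 0.00247 to 0.238 and for tri-snRNP proteins -0.0625 to 0.0666. For hnRNP and SR proteins it was -0.125 to -0.0265, for the RBM family -0.0525 to 0.105 and for lysosome genes -0.0452 to 0.119. Acinar and endocrine markers ranged from -0.137 to 0.465 and blood and endothelial markers from -0.38 to -0.203. The classical signature ranged from 0.07 to 0.643, the basal-like from -0.102 to 0.359, glycolysis from -0.0479 to 0.0993, embryonic kidney and neural markers from -0.291 to -0.043, cholesterol genes from 0.024 to 0.19 and ATF4 targets from -0.0793 to -0.00826. Translation factors ranged from -0.13 to -0.0511, PDAC oncogenes and tumour suppressors from 0.033 to 0.0818, p53 targets from 0.0845 to 0.188, histones from -0.89 to -0.3, snoRNA hosts from -0.539 to -0.302 and ribosome biogenesis from -0.312 to -0.17.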

Other observations

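The search for base words, the RNAs without a poly(A) tail, the reading of the G1/S list against the histones, and the fits without GCCCAA genes were chosen only after the results they bear on were seen. With the replicate block, the spliceosomal RNAs RNU2-2P (-0.53, SE 0.09), RNU4-1 (-0.36, SE 0.11) and RNU4-2 (-0.34, SE 0.11) and the RNA of RNase MRP, RMRP (-0.31, SE 0.10), were lower, with adjusted p of 0.000246, 0.0224, 0.0292 and 0.0277 in edgeR's test. Without the block their adjusted p lay between 0.597 and 0.751. The RNAs RN7SK, RPPH1, TERC, RN7SL1, RN7SL2 and RN7SL3 were not called in either fit.

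With genes holding GCCCAA left out and genes that were not searched kept, camera with its preset correlation called p53 targets and interferon-stimulated genes higher. Their medians were 0.24 (camera adjusted p = 0.0463) and 0.19 (0.0463), and with the block 0.24 (0.0451) and 0.21 (0.0142). Neither list was called with an estimated correlation (adjusted p = 0.725 and 0.823, and 0.756 and 0.799 with the block). With all genes the adjusted p was 0.32 and 0.332. In the blocked fit of all genes, the median of p53 targets was -0.18 in the 16 members with the bases and 0.27 in the 12 without them. GC content and length trends were removed from none of these values, which may also reflect those trends.

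Genes whose mRNA held GCCCAA were lower. In 9737 genes compared, the 5234 with these bases had z = -19.52, the lowest of all words of 6 bases. That z ranks blocked log2 fold changes after removal of trends on the GC content and length of the mRNA. Medians of these adjusted values were 0.047, -0.015, -0.055 and -0.112 in genes with 0, 1, 2 and 3 or more copies. The share called lower with the block, without that removal, was 11.4%, 21.3%, 30.4% and 41.4%. These shares may also reflect GC content and length. Base composition as the whole cause was argued against, since of the 60 orders of the same bases the next lowest, AGCCCA, had z = -7.596. Off-target silencing through a seed match of the hairpin is a candidate explanation: GCCCAAA, the lowest word of 7 bases on odd-numbered autosomes, had z = -11.83 in the 4405 held-out genes, although those genes were among the data in which the word was first noticed. The mRNA of RBM42 held GCCCAA in exon 2 of 10, in the coding sequence (hg38 chromosome 19, 35629642 to 35629647, plus strand), while the hairpin's sequence is not given in the sources used here. The word GCCCAAA was not in the RBM42 mRNA, nor were the next lowest, TGCCCAA (z = -15.91) and AGCCCAA (z = -15.18). That mRNA held the rarer CGCCCAA (z = -11.97, 689 genes), CCGCCCA (z = -11.07, 1563 genes) and GCCCAAT (z = -9.23, 1072 genes). The other words among the 10 lowest were not in it. As 53.75% of the compared genes held GCCCAA, the presence of these 6 bases alone in RBM42 says little about the hairpin. With the bases in the coding sequence only, the adjusted median was -0.0269 (2608 genes), and in the 3' UTR only -0.0225 (1559 genes). It was -0.112 in 1067 genes with the bases in both and 0.0468 in 4503 genes with them in neither. RNA stability that depends on RBM42 and acts through the same bases cannot be told apart from off-target silencing, because the libraries hold 1 way of lowering RBM42.

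Replication-dependent histone genes were lower, with a median of -0.59 (SD of members 0.292) with the block. GC content and length trends as the whole cause were argued against, since the median was -0.467 (SD 0.272) after their removal. Camera's adjusted p was then 1.4e-15 at the preset correlation. With the block, an estimated correlation and the trends kept, the histone list was not called (camera adjusted p = 0.811). Lower capture of RNAs without a poly(A) tail as the whole cause was argued against, since 10 such RNAs had a median of -0.068 (SD 0.247). They are not 10 independent RNAs: RN7SL1, RN7SL2 and RN7SL3 (0.109 to 0.177) are copies of 7SL, and RNU4-1 and RNU4-2 both encode U4. RNU2-2P (-0.526) was near the histones, and RNU4-1 (-0.361), RNU4-2 (-0.336) and RMRP (-0.309) were lower too, so a part of the decrease may come from capture. Fewer cells in S phase may account for it and stays open: the G1/S list had a median of -0.243 with the block (adjusted p = 0.000387) and -0.154 after removal of GC content and length trends, with an adjusted p of 0.811 with an estimated correlation, and no count of cells by phase was used here.

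Libraries with the same replicate number deviated together, with a mean correlation of 0.494. The mean was 0.485 without structural RNA genes, so the values of those genes did not carry it. Whether their differing shares of the counts play a part could not be decided, as 20130 of 20601 genes stayed and both fits were TMM-scaled. Those shares went with the replicate number: 14.1%, 19.9% and 7.35% in shSCR replicates 1, 2 and 3. In shRBM42-1 they were 14.1%, 18.2% and 9.53%. GC content and length trends were argued against as the whole cause of the correlation, with a mean of 0.476 after their removal. A shared culture or library batch was not tested and stays open, since the labels give no batch.

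The 6 libraries can be split into groups of 3 in 10 ways, which are too few for a share under 0.05. For genes higher, genes lower and genes changed at least 2-fold, 1 of 10 splits, the real one, gave as many, with 30, 116 and 91 against 0 as the highest of the others. For lists called, 7 of 10 splits gave as many as the real 5, and the highest other gave 14. The splits that kept 2 of the replicate numbers together gave 5 to 14 lists and the others that parted all 3 pairs gave 0 to 3, which points to a structure of the libraries by replicate number. With the block, 4 splits part all 3 pairs, again too few, and 1 of 4 gave as many genes as the real 4945, with 0 as the highest other and 2 to 3 lists against 6.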
